A study of Homo sapiens with 76 samples.

How the data were processed

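T47D cells with a stable control hairpin or a stable hairpin against RING1B were deprived of hormone for 3 days, without or with 45 minutes of E2 at the end. RNA-seq covered 4 groups of 2 libraries, which were prepared as stranded total RNA. 4C-seq from a viewpoint at GREB1 covered the same 4 groups with 1 library each. The other data types of the series were not used here. Samples were grouped by their titles. For the 4C libraries the growth descriptions name the shRING1B line and E2 for every sample, in conflict with the titles, so the 4C grouping rests on the titles.

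Per the submitters' processing notes, cutadapt 2.3, STAR 2.6.1a and RSEM 1.3.0 were among the tools used with the hg19 build, without a role given for each. The deposited gene tables held RSEM's expected counts, which are estimated reads per gene before any normalisation. Per the file headers the same tables also held TPM and FPKM as computed by the authors, and both were left unused. Per the file headers they gave an effective length for each gene, which served in 1 alternative only. The 4C files held a signal normalised by the authors by a method that is not stated, as a running median over 48 window widths that carry no label, with upper and lower quantiles beside it. No chromosome was given for the positions.

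The gene tables held 57820 identifiers, of which 52037 matched a current symbol. Symbols are printed as in the tables, so CYR61 stands for CCN1 and CTGF for CCN2. The labels name ERCC spike-ins, but the tables held no entries for them, so scaling by spike-ins was not run. The strand used for counting is not stated, so antisense and overlapping genes are uncertain, as are close paralogs.

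Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 18428. Libraries were scaled by TMM, and a robust quasi-likelihood model with 1 term per group was fitted to all 8 libraries. The comparisons were shRING1B against shCtrl without and with E2, E2 against hormone deprivation in each line, the interaction, and the averages of either effect. p values were adjusted by Benjamini and Hochberg, and an adjusted p under 0.05 was called. Log2 fold changes are given with their SE, and CPM with the SD of 2 libraries, after TMM scaling.

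Total estimated counts, replicate 1 then replicate 2, were 19026797 and 18890985 in hormone-deprived shCtrl, 17211665 and 15866732 in hormone-deprived shRING1B, 19792150 and 16530029 in shCtrl with E2, and 15601854 and 17015779 in shRING1B with E2. Replicates correlated at 0.975 to 0.983 on log2 CPM. Their spread was 8.53 to 42.2 times that of counting alone, as chi-square per degree of freedom. The median SD between replicates was 0.12 to 0.18 on the log2 scale. The procedure was tested on simulated counts of this design. Changed genes were drawn only from those above a minimum mean count, and the noise was independent between genes. Recovery is therefore not known for genes with fewer counts, or where genes share replicate differences. Each comparison held 68 genes changed by 1.5-fold, 66 by 2-fold and 66 by 4-fold. With fewer changed genes the adjusted threshold is stricter and recovery may be lower. For shRING1B against shCtrl the procedure recovered 22.1% of genes changed by 1.5-fold, 80.3% at 2-fold and 93.9% at 4-fold, with 10 false calls among 140. For E2 in shCtrl these were 26.5, 80.3 and 93.9%, for E2 in shRING1B 25.0, 80.3 and 97.0%, and for the interaction 7.35, 50.0 and 95.5%.

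Replicate numbers were not used as pairs. The difference between replicates 1 and 2 correlated at 0.59 to 0.72 among 3 of the groups, over 10331 genes with a mean log2 CPM above 3, but at -0.26 to -0.098 with shRING1B with E2. Over all 18428 genes the correlations were 0.14 to 0.22 and -0.11 to -0.049.

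Before the data were examined, 25 lists of genes, the comparisons, the rule for naming genes and the alternatives were written down, except where the text says otherwise. The lists covered the early estrogen response, immediate early genes, PRC1 and PRC2 subunits, HOX genes, developmental regulators, receptor cofactors, looping factors, R-loop factors, luminal genes, basal and mesenchymal genes, fibroblast and immune genes, G2/M and G1/S genes, p53 targets, the interferon response, the unfolded protein and integrated stress response, heat shock, hypoxia and glycolysis, cholesterol synthesis, NF-kB targets, Notch, WNT and BMP targets, genes near GREB1, ribosomal proteins and replication histones. They held 718 genes, of which 705 were matched. Each list was tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the 25 lists. The response of E2-responsive genes was compared between lines with fry, over the genes called on the averaged effect and oriented by its sign.

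Genes were named by rule. RNF2, RING1, GREB1, ESR1, TFF1, PGR and MYC were followed in every comparison. In each comparison the 10 largest increases and 10 largest decreases were eligible among called genes with a symbol and a mean log2 CPM of at least 1, with both libraries of 1 group above both of the other. Up to 4 members of each list with the smallest p were eligible too. Mitochondrial and ribosomal RNA genes were not named. The text names a part of the eligible genes.

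For 4C, the smallest window width was used. Positions within 10 kb of the viewpoint were left out, and the share of the remaining signal 25 to 100 kb from the viewpoint was compared on each side. The planned classes of 25 to 50 and 50 to 100 kb were joined for this. Classes planned beyond 100 kb could not be filled.

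The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, filters, thresholds and gene sets, the compared libraries alone, a replicate block, effective-length offsets, leaving out each library, an estimated correlation or fry for the lists, and other widths, exclusions and scaling for 4C. A crossed replicate block, a fit without abundant structural RNAs and the smallest 4C width over the positions of the largest were added after the data were seen. statmod 1.5.0 supplied the robust estimation.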

Results

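The experiments asked how the loss of RING1B changed estrogen-dependent gene expression in T47D cells, an estrogen receptor-positive line of luminal breast carcinoma. RING1B, encoded by RNF2, is the ubiquitin ligase of Polycomb repressive complex PRC1. Stable lines carried a control hairpin (shCtrl) or a hairpin against RING1B (shRING1B). Both were deprived of hormone for 3 days and collected directly or after 45 minutes of estradiol (E2). Total RNA was sequenced from 2 libraries in each of these 4 groups, and the contacts of the GREB1 locus were profiled by 4C-seq, which ligates and sequences the fragments that lie near a chosen viewpoint, in 1 library per group. The ATAC-seq, ChIP-seq and R-loop profiles of the study were not analysed here.

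The 8 RNA libraries held 15601854 to 19792150 estimated counts. The common coefficient of variation of a gene between replicates, as estimated by edgeR, was 13.3%. The signal recognition particle RNAs RN7SL1 and RN7SL2 took 15.9 to 20.1% of the counts in shCtrl and 10.4 to 12.04% in shRING1B. Mitochondrial ribosomal RNA took 0.826 to 2.82%. The leading principal component held 54.4% of the variance and separated the shRNA lines, while along the next (13.7%) lines and hormone states overlapped.

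RNF2 (ENSG00000121481.6) was lower in every shRING1B library than in every shCtrl library. In hormone-deprived cells its level in CPM, counts scaled to the size of the library, was 14.4 ± 2.77 in shCtrl and 4.79 ± 1.28 in shRING1B (SD, n = 2 libraries here and throughout). After E2 the levels were 13.3 ± 1.11 and 4.76 ± 0.750. The log2 fold change was -1.58 ± 0.23 (SE, as for all fold changes) without E2 and -1.49 ± 0.23 with E2, with adjusted p 0.00103 and 0.00154 in edgeR's quasi-likelihood test. The level of the paralog RING1 did not pass the threshold, at 0.22 ± 0.13 and 0.27 ± 0.13 (adjusted p 0.270 and 0.181). Without replicate 1 of the hormone-deprived shCtrl group, RING1 rose by 0.43 with adjusted p 0.0447.

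In hormone-deprived cells ESR1, MYC and KRT8 were lower in shRING1B than in shCtrl. ESR1 (ENSG00000091831.17), which encodes the estrogen receptor, fell from 151 ± 9.18 to 78.3 ± 6.06 CPM (-0.95 ± 0.10 on the log2 scale, adjusted p 2.25e-04). MYC fell from 18.2 ± 2.39 to 3.51 ± 0.131 CPM (-2.37 ± 0.14, adjusted p 8.57e-06). KRT8, a keratin of luminal cells, fell from 11810 ± 2777 to 2484 ± 29.5 CPM. In all, 2068 genes were higher and 2162 lower in shRING1B among 18428 tested (edgeR, adjusted p under 0.05), and 734 and 957 of them changed by more than 1 on the log2 scale. These counts were lower when either hormone-deprived shRING1B library was left out, at 2430 genes without replicate 1 and 2507 without replicate 2.

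**Figure D1:**
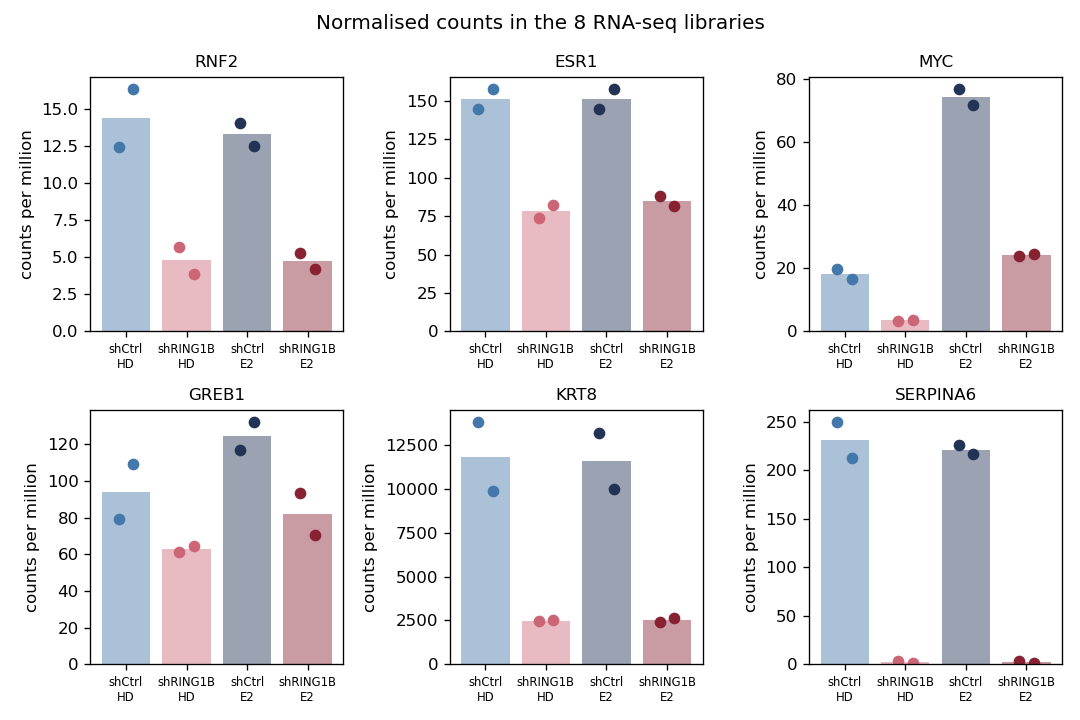
Normalised expression (CPM) of 6 genes in the 8 RNA libraries, with points for libraries and bars for the means of 2 libraries. RNF2, ESR1, KRT8 and SERPINA6 were lower in both shRING1B groups, and MYC rose with E2 in both lines.

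Among the genes with the largest increases without E2, SLITRK6, a neuronal transmembrane protein, rose from 2.38 ± 0.579 to 152 ± 7.37 CPM (log2 fold change 5.99 ± 0.24). The membrane metalloprotease gene MMP16 rose by 4.61 ± 0.21 and CRISP3 by 4.44 ± 0.20. The lipid transporter gene ABCA12, POF1B and the BMP receptor gene BMPR1B rose by 4.13 ± 0.23, 4.13 ± 0.29 and 4.08 ± 0.21. KCNJ3, which encodes a potassium channel, rose by 4.82 ± 0.40 from at most 8 counts per shCtrl library. BCHE, the gene of butyrylcholinesterase, had at most 4 counts in any hormone-deprived shCtrl library and 20.9 ± 3.04 CPM in shRING1B.

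The largest decreases without E2 included SERPINA6, KRT4 and AZGP1. SERPINA6, which encodes the corticosteroid-binding globulin, fell from 231 ± 26.4 to 2.62 ± 1.12 CPM (-6.44 ± 0.29). HSD17B1, whose product makes estradiol from estrone, changed by -4.24 ± 0.20, and ALDH1A3, an enzyme of retinoic acid synthesis, by -4.21 ± 0.20. The epithelial genes KRT4, IVL and S100A14 changed by -5.80 ± 0.21, -3.90 ± 0.24 and -3.98 ± 0.36. The secreted glycoprotein gene AZGP1, the bradykinin receptor gene BDKRB2 and the protease inhibitor gene TIMP3 changed by -4.90 ± 0.29, -4.38 ± 0.14 and -4.21 ± 0.19. PSG9 was at 25.0 ± 0.429 CPM in shCtrl and at most 3 counts per library in shRING1B. Near-identical paralogs of PSG9 make its level uncertain.

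Most genes of the interferon response list were higher in shRING1B. Of 33 tested genes of the interferon response list, 21 were higher and 1 was lower (camera adjusted p 1.64e-07 with a preset correlation among genes, but 0.193 with one estimated from the data). Adjusted over the list alone, 24 were higher and 1 lower. IFIT1 and OAS1, antiviral effectors, rose by 2.87 ± 0.26 and 2.76 ± 0.31, and IRF9, a subunit of the interferon-activated transcription complex, by 1.77 ± 0.20. The transcription factor gene IRF1 went the other way, at -1.38 ± 0.14. The level of IFIT1 was low even in shRING1B, at 7.93 ± 0.290 CPM.

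Of the called genes in the immediate early, hypoxia and HOX lists most or all were lower. With an estimated correlation none of these 3 list results passed (adjusted p 0.196, 0.193 and 0.193). Of 31 immediate early genes 17 were lower and 0 higher (19 and 0 adjusted over the list alone, camera adjusted p 2.68e-07), with BTG2 at -2.01 ± 0.14, CYR61 at -2.19 ± 0.16, PHLDA1 at -2.31 ± 0.17 and the phosphatase gene DUSP1 at -1.77 ± 0.17. Of 25 hypoxia and glycolysis genes 12 were lower and 1 higher (12 and 2 adjusted over the list alone, adjusted p 5.06e-06), with NDRG1 at -3.87 ± 0.17, the mTOR inhibitor gene DDIT4 at -2.58 ± 0.17, and the glycolytic genes PFKFB3 and LDHA at -2.14 ± 0.16 and -1.45 ± 0.14. Of 14 tested HOX genes, classical Polycomb targets, 9 were lower and 0 higher (12 and 0 adjusted over the list alone, adjusted p 1.26e-05). HOXC13, HOXB2 and HOXB3 changed by -1.50 ± 0.15, -1.26 ± 0.15 and -1.57 ± 0.19, and HOXB4, with at most 7 counts in any shRING1B library, by -2.94 ± 0.52.

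The early estrogen response and luminal lists held genes that changed in both directions, more of them lower. With an estimated correlation neither list passed (adjusted p 0.654 and 0.919). Of 54 early estrogen response genes 20 were lower and 9 higher (camera adjusted p 0.0188), and adjusted over the list alone 23 were lower and 11 higher. STC2, the scaffold gene PDZK1 and the Hippo pathway gene WWC1 changed by -2.84 ± 0.11, -3.35 ± 0.20 and -1.41 ± 0.099. TFF1 changed by -2.27 ± 0.38 from only 3.69 ± 0.410 CPM, while PGR, which encodes the progesterone receptor, rose by 1.02 ± 0.20. GREB1 (ENSG00000196208.9) changed by -0.59 ± 0.17 (adjusted p 0.0407), a call lost with a replicate block (-0.58, adjusted p 0.0540), upper-quartile scaling (adjusted p 0.0553), the 4 libraries alone (0.0587) and effective-length offsets (0.0622). It was also lost without replicate 2 of hormone-deprived shCtrl (-0.34, adjusted p 0.179), without replicate 1 or 2 of hormone-deprived shRING1B (adjusted p 0.163 and 0.123) and without replicate 1 or 2 of shCtrl with E2 (0.0552 and 0.0546). Of 21 luminal genes 11 were lower and 2 higher (11 and 3 adjusted over the list alone, adjusted p 0.0199), with ELF3, KRT8 and KRT18 at -2.14 ± 0.13, -2.25 ± 0.20 and -2.09 ± 0.20, and AGR3 at 1.89 ± 0.18. Both list results depended on replicate 1 of the hormone-deprived shRING1B group, without which the adjusted p was 0.0518 and 0.0667, and that of the early estrogen response also on replicate 2 of the hormone-deprived shCtrl group (0.0825).

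Single members of other lists changed in both directions. Among PRC1 subunits, CBX6 and RYBP rose by 2.04 ± 0.15 and 0.79 ± 0.13. The receptor cofactor gene NRIP1 rose by 0.96 ± 0.097. SOX2 rose by 4.22 ± 0.45 from at most 9 counts per shCtrl library and MSX2 changed by -1.30 ± 0.11. EGFR of the basal list changed by -1.51 ± 0.16, and FN1 and TWIST1 by 1.01 ± 0.15 and 1.75 ± 0.31. The cell-cycle inhibitor gene CDKN1A and MDM2 rose by 1.16 ± 0.13 and 0.72 ± 0.10, while GDF15, also a p53 target, changed by -2.24 ± 0.28. The amino-acid transporter gene SLC7A5 changed by -3.39 ± 0.19 and ASNS by 1.18 ± 0.11, the R-loop helicase gene DDX21 by -0.86 ± 0.14, the mitotic gene HMMR by -0.94 ± 0.16, the chaperone gene HSPB1 by -1.16 ± 0.17, the WNT target AXIN2 by -2.47 ± 0.34 and CYS1, a neighbour of GREB1, by -3.07 ± 0.26. RPL19, whose reads processed pseudogenes may share, changed by -1.20 ± 0.17.

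Of the lists behind those genes, only the G2/M list passed, with 3 of 30 genes lower (2 over the list alone, adjusted p 0.0188, or 0.919 with an estimated correlation), and not with DESeq2 (0.169), with fry (0.274) or without replicate 1 of the hormone-deprived shRING1B group (0.210). The counts higher and lower, with those adjusted over the list alone in brackets, were 4 and 3 of 29 (4 and 4) for PRC1 subunits, 2 and 0 of 12 (0 and 0) for PRC2 subunits, 3 and 3 of 33 (3 and 3) for developmental regulators, 4 and 2 of 23 (4 and 2) for receptor cofactors, 0 and 1 of 21 (0 and 0) for looping factors and 1 and 3 of 30 (1 and 3) for R-loop factors. They were 4 and 3 of 14 (4 and 4) for basal and mesenchymal genes, 3 and 2 of 32 (2 and 0) for G1/S genes, 7 and 3 of 22 (9 and 5) for p53 targets, 8 and 9 of 27 (8 and 9) for the unfolded protein and integrated stress response, 1 and 4 of 15 (1 and 4) for heat shock and 2 and 3 of 24 (2 and 3) for cholesterol synthesis. For NF-kB targets they were 0 and 5 of 14 (2 and 5), for Notch, WNT and BMP targets 3 and 4 of 17 (3 and 4), for genes near GREB1 1 and 4 of 14 (1 and 5), for ribosomal proteins 1 and 1 of 40 (1 and 1), for replication histones 0 and 1 of 12 (0 and 1) and for fibroblast and immune genes 2 and 0 of 5 (2 and 0). Without replicate 2 of hormone-deprived shCtrl, heat shock (adjusted p 0.0336), ribosomal proteins (2.71e-06) and replication histones (0.0434) passed as lower, and ribosomal proteins also without replicate 1 of hormone-deprived shRING1B (0.0218). In the fibroblast list, LUM and COL3A1 were at 0 counts in both hormone-deprived shCtrl libraries and at most 17 and 13 counts in shRING1B. Median and mean differed in sign for receptor cofactors, basal, fibroblast, NF-kB and Notch lists, and for cholesterol synthesis the test went against both. No list in any comparison kept an adjusted p under 0.05 when the correlation among its genes was estimated from the data. That setting also makes camera use the residual degrees of freedom of the few libraries, which raises p by itself. Notch, WNT and BMP targets in the interaction had an estimated correlation of -0.031, under the preset 0.01, yet camera's p went from 1.72e-05 to 0.0098. A loss with an estimated correlation is therefore not a measure of correlation alone.

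With E2 present the difference between the lines was similar in size and in its leading genes. Of 18428 genes, 2002 were higher and 2170 lower in shRING1B. In all 4172 were called, against 2340 without replicate 1 and 2643 without replicate 2 of shCtrl with E2, and 2203 and 2150 without those of shRING1B with E2. The comparisons share no library, and 1580 genes were higher in both (225 if the lists were independent) and 1790 lower in both (255), with 1 gene called in opposite directions. ESR1 changed by -0.84 ± 0.10 (adjusted p 4.58e-04), or by -0.52 with effective-length offsets (adjusted p 0.0589), and MYC by -1.61 ± 0.12. TFF1 and PGR changed by -2.22 ± 0.37 and 0.84 ± 0.20, and PGR was not called without replicate 1 of shCtrl (adjusted p 0.0928), replicate 1 of shRING1B (0.110) or replicate 2 of shRING1B (0.0545), each with E2. GREB1 changed by -0.60 ± 0.17 (adjusted p 0.0364), which did not pass with upper-quartile scaling (adjusted p 0.0512), nor without replicate 2 of shRING1B with E2 (-0.42, adjusted p 0.231), replicate 1 or 2 of shCtrl with E2 (0.0801 and 0.163) or replicate 1 or 2 of hormone-deprived shRING1B (0.0556 and 0.0566).

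SLITRK6, MMP16, CRISP3, BMPR1B and ABCA12 were again among the largest increases with E2 present, at 5.77 ± 0.23, 4.92 ± 0.22, 4.42 ± 0.20, 4.41 ± 0.21 and 4.04 ± 0.23, and CBLN2 rose by 3.71 ± 0.21. SERPINA6, KRT4, HSD17B1, ALDH1A3, BDKRB2 and TIMP3 changed by -6.46 ± 0.29, -5.58 ± 0.21, -4.28 ± 0.20, -4.26 ± 0.20, -4.26 ± 0.14 and -4.23 ± 0.19. Interferon genes were again higher, with IFIT1 at 2.73 ± 0.24 and OAS1 at 2.85 ± 0.31. NDRG1, STC2 and PDZK1 changed by -3.71 ± 0.17, -2.71 ± 0.11 and -3.40 ± 0.21, the immediate early gene IER3 by -2.13 ± 0.19 and HOXB2 by -1.32 ± 0.15. The luminal gene TFF3 changed by -1.10 ± 0.10, and the BMP target ID1 rose by 1.35 ± 0.13.

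The lists that passed camera's test with E2 present, with genes higher and lower and in brackets those adjusted over the list alone, were the interferon response at 19 and 1 of 33 (24 and 1), adjusted p 2.51e-08, immediate early genes at 1 and 17 of 31 (1 and 17), adjusted p 1.39e-07, hypoxia and glycolysis at 2 and 14 of 25 (2 and 14), adjusted p 4.28e-06. HOX genes were at 0 and 9 of 14 (0 and 11), adjusted p 1.07e-04, the early estrogen response at 9 and 22 of 54 (9 and 25), adjusted p 3.96e-04 and G2/M genes at 0 and 4 of 30 (0 and 4), adjusted p 0.0283. With an estimated correlation none of these 6 passed, at adjusted p 0.198 for the first 4 lists, 0.276 for the early estrogen response and 0.932 for G2/M genes. The fry test asks whether a list changed at all, while camera compares it with the other genes. With 4172 genes called between the lines, a pass with fry need not be particular to a list. The G2/M list did not pass with DESeq2 (adjusted p 0.164), the strict low-count filter (0.0505) or fry (0.307), nor without replicate 1 of shRING1B with E2 (0.669). Luminal genes did not pass (2 and 10 of 21 (4 and 10), adjusted p 0.0664), but did with DESeq2 (1.63e-05), without the low-count filter (0.0189), with effective-length offsets (0.0363), with fry (0.0198) and without replicate 2 of shCtrl (0.0361) or of shRING1B (0.00808), each with E2. Genes near GREB1 did not pass either, but did as lower without the low-count filter (0.0117), with effective-length offsets (0.0363), with fry (8.56e-04) and without the same libraries (0.0400 and 0.0411), and ribosomal proteins without replicate 2 of shCtrl with E2 (0.00870).

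Few genes were called after 45 minutes of E2 in shCtrl cells, and MYC had the largest fold among them. MYC (ENSG00000136997.10) rose from 18.2 ± 2.39 to 74.2 ± 3.55 CPM (2.03 ± 0.12 on the log2 scale, adjusted p 2.31e-04). CYP1B1, an estrogen-hydroxylating enzyme gene, and TIPARP, an ADP-ribosyltransferase gene, rose by 1.85 ± 0.13 and 1.74 ± 0.095. KCTD6, CISH, a feedback inhibitor of cytokine signalling, and GADD45B rose by 1.54 ± 0.11, 1.49 ± 0.15 and 1.40 ± 0.14. These were the 6 genes called higher by edgeR, with 0 lower, against 25 by DESeq2 and 566 at an unadjusted p under 0.05, where chance gives 921. With only the 4 libraries compared KCTD6, CISH and GADD45B were not called (adjusted p 0.0594, 0.167 and 0.182), nor was CISH with effective-length offsets (0.247). CISH was also not called without replicate 2 of shCtrl with E2 (adjusted p 0.0788) and GADD45B not without replicate 1 of it (0.0612), while 12 genes were called without replicate 1 of the hormone-deprived shCtrl group.

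GREB1, PGR and TFF1, the classical targets, were not called after E2 in shCtrl, at 0.40 ± 0.17, 0.68 ± 0.20 and 0.31 ± 0.33 (adjusted p 1 each). Without the low-count filter PGR was called (0.66, adjusted p 3.40e-04). RNF2 changed by -0.11 ± 0.21, and the fold of ESR1 was below its SE of 0.10. The early estrogen response list rose, with a median of 0.29 over 54 genes (camera adjusted p 1.44e-25, or 0.0592 with an estimated correlation), and 14 members were higher adjusted over the list alone. BHLHE40 and SLC22A5 of that list were at 0.70 ± 0.090 and 0.81 ± 0.11 and were not called (adjusted p 0.0552 and 0.0552), but were with a replicate block (0.0224 and 0.0315), with DESeq2 (9.30e-05 and 4.90e-04) and with other gene filters. Immediate early genes had a median of 0.46 (adjusted p 1.48e-04, but 0.566 with an estimated correlation and 0.198 with fry), with KLF10 at 0.87 ± 0.14 and JUNB at -0.77 ± 0.13, and 6 members were higher and 3 lower adjusted over the list alone. Over all genes neither of the 2 was called except without the low-count filter (0.00116 and 3.43e-05) and, for JUNB, with DESeq2 (0.00939). That list did not pass without replicate 2 of shCtrl with E2 (adjusted p 0.204). Receptor cofactors, with RARA at 0.70 ± 0.17, also passed (median 0.12, adjusted p 7.17e-04), as did heat shock (-0.12), ribosomal proteins (-0.17) and replication histones (-0.15). No member of these 4 lists was called, and none of the 4 passed with an estimated correlation (adjusted p 0.931, 0.566, 0.931 and 0.931) or with fry (0.934 each). Without replicate 1 of the hormone-deprived shCtrl group the medians of these 4 lists were -0.045, 0.027, 0.13 and 0.037, and without replicate 2 of shCtrl with E2 -0.029, -0.014, -0.013 and -0.052. Developmental regulators passed upward without replicate 2 of the hormone-deprived shCtrl group (adjusted p 0.0183).

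In shRING1B cells E2 again raised MYC, CISH, CYP1B1 and TIPARP. MYC rose from 3.51 ± 0.131 to 24.2 ± 0.631 CPM (2.78 ± 0.14, adjusted p 1.11e-04) and CISH by 2.40 ± 0.18. CYP1B1 and TIPARP rose by 1.50 ± 0.12 and 1.32 ± 0.094. The Notch target HES1, the circadian repressor gene BHLHE40 and KRT15 were also called, at 1.04 ± 0.12, 0.91 ± 0.091 and 0.86 ± 0.11, but none of the 3 was with effective-length offsets (adjusted p 0.141, 0.124 and 0.417), nor KRT15 with limma-voom (0.129). edgeR called 7 genes higher and 0 lower, against 23 by DESeq2 and 563 at an unadjusted p under 0.05, where chance gives 921. 4 of the 7 were also called in shCtrl (0.00228 for independent lists). Without replicate 1 or 2 of hormone-deprived shRING1B 4 genes were called, and HES1 (adjusted p 0.460 and 0.320), BHLHE40 (0.283 and 0.203) and KRT15 (0.460 and 0.368) did not pass. Without replicate 1 or 2 of shRING1B with E2, BHLHE40 (0.0922 and 0.250) and KRT15 (0.389 and 0.551) did not pass, nor HES1 without replicate 2 (0.284). Without replicate 1 or 2 of shCtrl with E2, HES1 (0.0858 and 0.0776) and KRT15 (0.105 and 0.109) did not pass.

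KCTD6 and GADD45B were at 0.59 ± 0.11 and 0.98 ± 0.16 in shRING1B and not called, but GADD45B was with DESeq2 (adjusted p 0.00719) and without the low-count filter (4.48e-06). GREB1, PGR and TFF1 were at 0.38 ± 0.17, 0.50 ± 0.20 and 0.36 ± 0.43 (adjusted p 0.98 each), and PGR was called without the low-count filter (0.49, adjusted p 0.0430). The early estrogen response list rose by a median of 0.18 (camera adjusted p 1.95e-11, or 0.162 with an estimated correlation) and immediate early genes by 0.23 (adjusted p 1.51e-05, but 0.404 with an estimated correlation and 0.135 with fry), with 7 members of the latter higher and 1 lower adjusted over the list alone. CYR61 was at 0.85 ± 0.16, called with DESeq2 (0.0122) and without the low-count filter (8.70e-06) only. The Notch, WNT and BMP targets, with 1 of 17 called, had a median of 0.15 (adjusted p 3.05e-04, but 0.162 with an estimated correlation), with ID1, ID2 and ID3, the inhibitors of differentiation, at 0.74 ± 0.13, 0.53 ± 0.16 and 0.49 ± 0.14. None of these 3 was called, but ID1 was with DESeq2 (0.0222), without the low-count filter (1.95e-04) and with the 4 libraries alone (0.0319). Receptor cofactors (0.22), developmental regulators (0.31) and HOX genes (0.28) passed upward, and ribosomal proteins (-0.15) and replication histones (-0.11) downward. No member of these 5 lists was called, and none of the 5 passed with an estimated correlation (adjusted p 0.536, 0.536, 0.404, 0.676 and 0.676) or with fry (0.654, 0.654, 0.593, 0.786 and 0.761). Developmental regulators (adjusted p 0.0615) and ribosomal proteins (0.827) did not pass without replicate 1 of hormone-deprived shRING1B. HOX genes (0.244 and 0.140) and replication histones (0.933 and 0.583) did not pass without replicate 1 of shRING1B with E2 or replicate 2 of hormone-deprived shRING1B.

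Whether RING1B loss changed the response to E2 was tested by the interaction of hairpin and E2, and no gene passed in the planned fit. edgeR called 0 of 18428 genes, DESeq2 called 2 and the fit without the low-count filter 34, and 311 genes had an unadjusted p under 0.05, where chance gives 921. Leaving out replicate 1 of hormone-deprived shCtrl gave 4 genes, and leaving out its replicate 2 or replicate 2 of shCtrl with E2 gave 1 each. The interaction of MYC was 0.76 ± 0.19, that of TIPARP -0.42 ± 0.13, that of SLC22A5 -0.48 ± 0.15 and that of GREB1 -0.016 ± 0.25 (adjusted p 1 each). KCTD6 at -0.95 ± 0.16 and CISH at 0.91 ± 0.23 were chosen after their values were seen, and KCTD6 passed without the low-count filter (-0.94, adjusted p 0.0293). Although the fold of MYC was larger in shRING1B, its level after E2 stayed below that in shCtrl, at 24.2 ± 0.631 against 74.2 ± 3.55 CPM. In simulated data of this design, 50.0% of genes with an interaction of 2-fold and 7.35% with 1.5-fold were recovered. These were genes above a minimum mean count with independent noise, so recovery over all genes tested may be lower. It may also be lower where fewer genes change than were planted in the simulation.

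**Figure D2:**
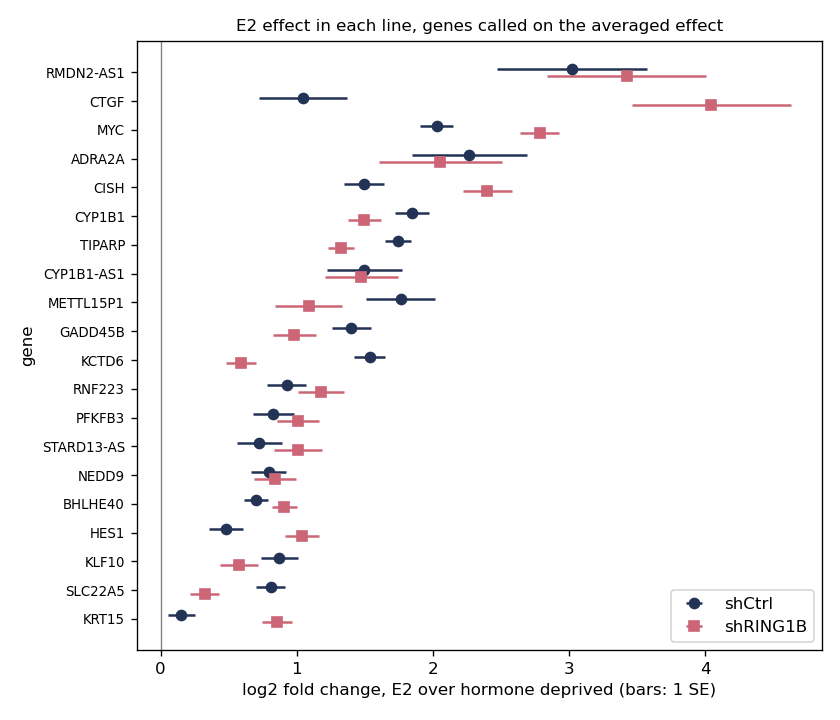
Log2 fold change with E2 in shCtrl (circles) and shRING1B (squares) for the 20 genes called on the effect averaged over both lines, with bars of 1 SE. The markers fall on either side of each other, with 9 of the 20 genes lower in shRING1B.

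Averaged over both lines, E2 raised 20 genes and lowered 0 in edgeR's test (65 called by DESeq2, 42 with a replicate block and 162 without the low-count filter), with MYC at 2.41 ± 0.094, CISH at 1.95 ± 0.12, CYP1B1 at 1.67 ± 0.089 and TIPARP at 1.53 ± 0.067. The count fell to 10 and 7 without replicates 1 and 2 of hormone-deprived shRING1B, to 12 and 8 without those of shRING1B with E2 and to 9 without replicate 2 of shCtrl with E2. Over these 20 genes the median interaction was 0.11, and 9 responded less in shRING1B (fry, adjusted over 3 gene sets, 0.406). The median response was 1.22 in shCtrl and 1.06 in shRING1B. The sign of the median interaction depended on single libraries, each with its own set of called genes. It passed fry's test at -0.40 without replicate 2 of shCtrl with E2, -0.090 without replicate 1 of the hormone-deprived shCtrl group and 0.30 without replicate 1 of shRING1B with E2. Without passing, it was -0.11 and -0.17 without replicates 1 and 2 of hormone-deprived shRING1B, -0.12 without replicate 2 of hormone-deprived shCtrl and -0.073 without replicate 2 of shRING1B with E2. For the early estrogen response list the median interaction in the same test was -0.025 (adjusted p 0.539), and for the 6 genes called in shCtrl it was -0.38 (0.311). The calls among the 20 included antisense transcripts next to CYP1B1, whose reads cannot be told apart from those of the opposite strand because the counting strand is not stated. Averaged over both hormone states, 3456 genes were higher and 3456 lower in shRING1B.

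The 4C profiles of GREB1 addressed whether its contacts changed with E2 and RING1B loss. The viewpoint was taken to be the middle of the listed positions, 11679984 (hg19 per the labels). Positions were given in steps of 1 kb up to 100 kb away on each side. With 1 library per group there was no replicate check and no test. At the smallest window width, 70.9% of the positions were at 0 in hormone-deprived shCtrl and 74.4% in hormone-deprived shRING1B. With E2 it was 48.2% in either line. Ratios of E2 over hormone deprivation thus compare libraries with unlike shares of zeros, and the part of this in the ratios was not tested. With 10 kb on each side of the viewpoint left out, 48.3% of the shCtrl signal lay 25 to 100 kb away on the side of lower coordinates without E2 and 65.6% with E2, a log2 ratio of 0.44. In shRING1B the same share went from 85.9 to 26.2% (-1.71). On the side of higher coordinates the share went from 32.2 to 12.1% in shCtrl (-1.42) and from 2.22 to 14.5% in shRING1B (2.71). In shCtrl the planned classes of 25 to 50 and 50 to 100 kb moved in opposite directions. On the lower side they went from 9.33 to 51.2% and from 38.9 to 14.3%. On the higher side they went from 3.10 to 4.60% and from 29.1 to 7.46%. In shRING1B both classes fell on the lower side and rose on the higher side.

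Of the 4 ratios, 2 changed direction with the window width. At the middle width, where values ended at -88 and 87 kb in place of -99 and 99 kb, the lower-coordinate share of shRING1B rose from 4.18 to 11.2% (1.42) and the higher-coordinate share of shCtrl from 0.269 to 4.05% (3.91). The others kept their direction, from 9.46 to 56.2% on the lower side of shCtrl (2.57) and from 0.760 to 9.99% on the higher side of shRING1B (3.72). With the smallest width limited to the positions that the largest width covers, a check added after the data were seen, the 4 directions were those of the smallest width. No direction of change in GREB1 contacts can be read from 1 library per group.

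**Figure D3:**
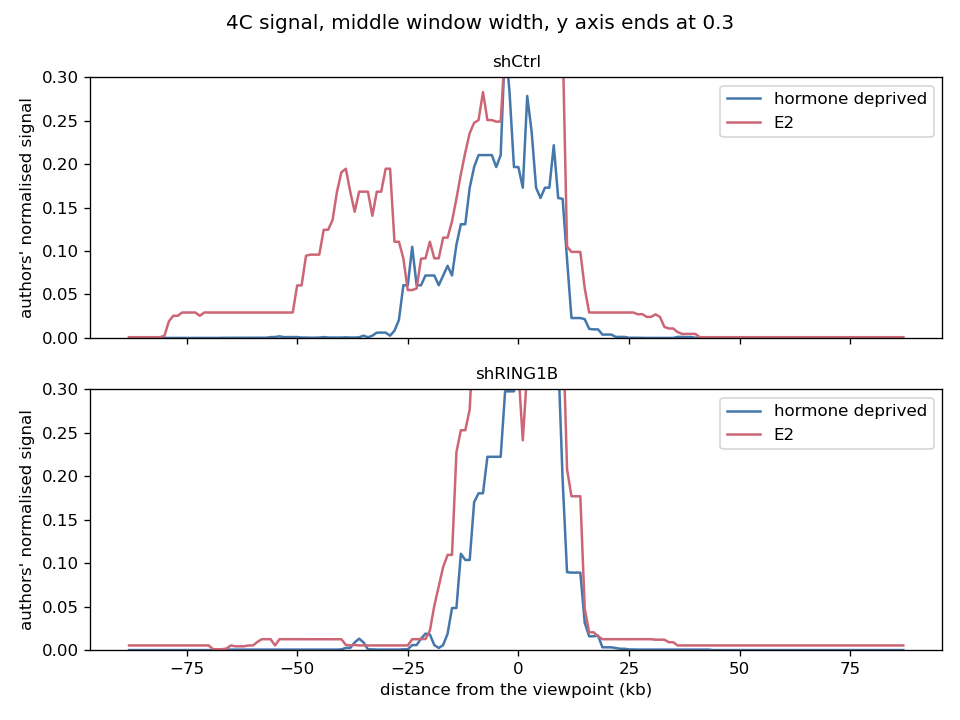
Normalised 4C signal around the GREB1 viewpoint at the middle window width, by distance in kb, for shCtrl (top) and shRING1B (bottom), without and with E2, 1 library each. The y axis ends at 0.3, so the signal next to the viewpoint runs off the plot.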

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

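The 3 list results below came from the planned interaction test, and the tests of structural RNAs, a property of the line, a shift shared by all genes, COL1A1 and its limit, library depth, exchanged replicate numbers and the limit on the splits were chosen only after the result was seen. The difference between lines in the response to E2, measured as an interaction, passed for 3 lists. The early estrogen response had a median of -0.067 (camera adjusted p 0.0494), lower in shRING1B. Developmental regulators had 0.21 (adjusted p 0.0494) and Notch, WNT and BMP targets 0.24 (adjusted p 4.30e-04), both higher. In the last, ID1, HES1, ID2 and ID3 had interactions of 0.87 ± 0.18, 0.56 ± 0.17, 0.58 ± 0.22 and 0.63 ± 0.20, and no single gene passed over all genes. Adjusted over the list alone 1 was higher, and ID1 passed without the low-count filter (0.88, adjusted p 0.0278).

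None of the 3 passed with an estimated correlation (adjusted p 0.945, 0.945 and 0.245) or with fry (0.986, 0.986 and 0.135). The first 2 also did not pass with limma-voom (0.0624 and 0.0543), upper-quartile scaling (0.0524 and 0.0524), effective-length offsets (0.208 and 0.377) or without the low-count filter (0.254 and 0.350). The early estrogen response did not pass without replicate 1 of hormone-deprived shCtrl (adjusted p 0.527), replicate 2 of hormone-deprived shRING1B (0.453), replicate 2 of shCtrl with E2 (0.533), or replicate 1 (0.101) or 2 (0.0510) of shRING1B with E2. Developmental regulators did not pass without replicate 1 of hormone-deprived shRING1B (0.801), replicate 2 of hormone-deprived shCtrl (0.717), replicate 1 (0.129) or 2 (0.0655) of shCtrl with E2, or replicate 1 of shRING1B with E2 (0.321).

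Over the 20 genes called on the averaged E2 effect, none of which passed the interaction test, those lower in shRING1B before E2 tended to have a larger interaction. Both were taken here as differences of log2 CPM between single libraries. The Spearman correlation was -0.624 with the level from replicate 1 and the interaction from replicate 2, and -0.645 the other way. This fits a lower starting level as a candidate explanation of the larger fold of genes such as MYC, though the genes are not independent of each other. The difference before E2 also enters the interaction with a negative sign. Separate replicates remove only variation that the libraries of a group do not share. A negative correlation can therefore arise without an effect of the starting level. Activation of the aryl hydrocarbon receptor, a possible source of the CYP1B1 and TIPARP response, stays open. Averaged over both lines, its targets AHRR, CYP1A1, CYP1A2 and NQO1 were at 0.29 ± 0.14, 1.83 ± 0.42, 0.40 ± 0.28 and -0.084 ± 0.094, and none passed (adjusted p 0.886, 0.731, 0.886 and 0.891). ALDH3A1 and UGT1A6 were not tested.

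TMM scaling centres the folds, at a median of 0.0096 without E2, so genes on both sides were to be expected. Their balance therefore does not test a shift shared by all genes. The spread of the folds does, since 734 genes were higher and 957 lower by more than 1 on the log2 scale without E2. A shift equal for all genes, such as one from the composition of the libraries, moves every fold alike. The spread thus argues against it as the whole cause of the difference between the lines. A smaller part from abundant structural RNAs stays open. Without RN7SL, RN7SK, MALAT1, mitochondrial and ribosomal RNA genes 4237 genes were called, but that fit moved no fold by more than 0.00166, under the smallest SE of 0.0844, so it tested nothing. RNA from fibroblasts as a possible source of LUM and COL3A1 stays open. COL1A1 was at -0.24 with an upper end (2 SE) of 0.31, but its own level of 19.4 CPM in shCtrl allows a rise of 4.62 CPM within that error, more than the 0.680 CPM of COL3A1 in shRING1B. A property of the selected line other than RING1B loss cannot be told apart from the effect of the hairpin, since each hairpin was in 1 line, and 505 called genes fell more than RNF2 did. Loss of RING1B itself stays among the open explanations.

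The replicate difference of shRING1B with E2 correlated negatively, but weakly, with those of the other groups. Gene length bias was argued against as the whole cause, while a part from it stays open. The replicate difference correlated with log gene length at -0.48 in hormone-deprived shCtrl and -0.36 in hormone-deprived shRING1B. With E2 it correlated at -0.36 in shCtrl and 0.068 in shRING1B. With a trend on length removed, the correlations of the replicate difference in that group with those of hormone-deprived shCtrl, hormone-deprived shRING1B and shCtrl with E2 went from -0.26, -0.098 and -0.26 to -0.26, -0.069 and -0.24, while the shCtrl groups correlated at 0.67. Exchanged replicate numbers stay open. After the exchange the highest correlation with another group was 0.26, against 0.59 to 0.72 among the other groups, which goes against an exchange. Mitochondrial ribosomal RNA goes with it, since it was higher in replicate 1 in that group (2.32 against 1.49%) and in replicate 2 in the others. The crossed replicate block, which makes the exchange, called 37 genes for E2 in shRING1B, against 7 in the main fit and 12 with the plain block. That block was added after the opposite replicate difference was seen and takes up that difference. More calls could follow without an exchange, so the block does not decide the question. Library depth remains a candidate explanation, since the library with more mitochondrial ribosomal RNA was the deeper one in 0 of the 4 groups. In a check also made after that result was seen, hormone-deprived shCtrl had the smallest depth ratio (1.01) and the largest median SD between replicates (0.18), an order that depth alone would not give. No biological explanation was tested.

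For the averaged E2 effect the splits could not give a share under 0.05, because the split by shRNA line, itself a factor of the design, is always among the 35 splits of the 8 libraries into 4 and 4. The real split called 22 genes, and 2 splits called at least as many, the other being the split by line with 7377, which points to the line as the main structure of the samples. The highest of the remaining splits called 2. For the averaged difference between lines 1 split, the real one, called 7453 genes, and the highest other called 1. None of the other splits had the line in the model, so the line difference counted as spread and kept their counts low. These splits therefore do not exclude chance, and with 1 line per hairpin the libraries do not replicate the line. The fits of the splits had additive terms for the split and the other factor. Their counts thus differ from the 20 and 6912 genes of the model with 1 term per group. A split equal to the other factor was fitted alone, so the split by E2 called 22 genes with the line in the model and 1 without it, and the split by line 7453 with E2 in the model and 7377 without it.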

How the results depend on the processing

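The crossed replicate block, the fit without abundant structural RNAs and the 4C ratios over the positions of the largest width were tests chosen only after the result was seen, and the others were planned. Of 3720 alternatives for named genes, 3632 kept their side of the threshold, 51 lost the call, 37 gained one and 0 reversed. Of 2475 for lists, 2311 kept it, 87 lost the call, 73 gained one and 4 reversed. A reversal was counted only where the main fit made a call, and never for the estimated correlation. Results without a call could change direction and still count as kept. Unless stated, the cause was not tested.

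The count between lines without E2 (4230) and with E2 (4172) was 2235 and 2244 at an adjusted p under 0.01, and 1691 and 1662 with a log2 fold change over 1, by construction of the stricter thresholds, which also gave 4506 and 2088 for the averaged difference (6912) and 8 and 12 for the averaged E2 effect (20). Without structural RNAs the count without E2 was 4237. For E2 in shCtrl (6), E2 in shRING1B (7), the interaction (0) and the averaged E2 effect, DESeq2 called 25, 23, 2 and 65, and omission of the low-count filter gave 108, 91, 34 and 162. With only the 4 libraries compared, E2 in shCtrl gave 3 and E2 in shRING1B 13. With a replicate block E2 in shRING1B gave 12 and the averaged E2 effect 42, and with the crossed replicate block E2 in shRING1B gave 37. Effective-length offsets gave 4 for E2 in shRING1B.

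Leaving out 1 library at a time leaves a lone sample that is assumed to vary like the other groups. It gave 2430 to 3874 genes between lines without E2, 2150 to 4809 with E2, 5 to 12 for E2 in shCtrl, 4 to 8 for E2 in shRING1B, 0 to 4 for the interaction and 7 to 29 for the averaged E2 effect. The median interaction of the E2-responsive genes went from -0.40 to 0.30.

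The list results that follow are medians on the log2 scale, whose sign can differ from the direction of the test. Unlike camera, fry does not compare a list with the other genes, so calls gained with it need not be particular to the list. For fibroblast and immune genes the calls gained with fry were upward, against negative medians. Their mean log2 fold change was 2.34 without E2 and 1.98 with E2, with 2 genes higher and 0 lower in each. An estimated correlation also makes camera use the residual degrees of freedom of the libraries, so a lost call need not stem from correlation. With an estimated correlation 30 calls were lost, for shRING1B without E2 early estrogen response -0.30, immediate early genes -0.86, HOX genes -1.17, luminal genes -0.49, G2/M genes -0.24, interferon response 0.89, hypoxia and glycolysis -0.43, for shRING1B with E2 early estrogen response -0.35, immediate early genes -0.75, HOX genes -1.17, G2/M genes -0.20, interferon response 0.82, hypoxia and glycolysis -0.46, for E2 in shCtrl early estrogen response 0.29, immediate early genes 0.46, receptor cofactors 0.12, heat shock -0.12, ribosomal proteins -0.17, replication histones -0.15, for E2 in shRING1B early estrogen response 0.18, immediate early genes 0.23, HOX genes 0.28, developmental regulators 0.31, receptor cofactors 0.22, Notch, WNT and BMP targets 0.15, ribosomal proteins -0.15, replication histones -0.11, for the interaction early estrogen response -0.067, developmental regulators 0.21, Notch, WNT and BMP targets 0.24. With fry in place of camera 16 were lost, for shRING1B without E2 G2/M genes -0.24, for shRING1B with E2 G2/M genes -0.20, for E2 in shCtrl immediate early genes 0.46, receptor cofactors 0.12, heat shock -0.12, ribosomal proteins -0.17, replication histones -0.15, for E2 in shRING1B immediate early genes 0.23, HOX genes 0.28, developmental regulators 0.31, receptor cofactors 0.22, ribosomal proteins -0.15, replication histones -0.11, for the interaction early estrogen response -0.067, developmental regulators 0.21, Notch, WNT and BMP targets 0.24, and 9 gained, for shRING1B without E2 fibroblast and immune genes -0.18, stress response -0.097, genes near GREB1 -0.16, for shRING1B with E2 luminal genes -0.30, fibroblast and immune genes -0.024, p53 targets 0.37, stress response -0.0079, Notch, WNT and BMP targets 0.48, genes near GREB1 -0.22. With DESeq2 2 were lost, for shRING1B without E2 G2/M genes -0.26, for shRING1B with E2 G2/M genes -0.21, and 4 gained, for shRING1B without E2 stress response -0.11, for shRING1B with E2 luminal genes -0.31, stress response -0.021, for E2 in shRING1B heat shock -0.10. With limma-voom 2 were lost, for the interaction early estrogen response -0.089, developmental regulators 0.22, and with upper-quartile factors 2, for the interaction early estrogen response -0.068, developmental regulators 0.22. Without the low-count filter 4 were lost, for E2 in shRING1B HOX genes 0.055, replication histones -0.11, for the interaction early estrogen response -0.054, developmental regulators 0.22, and 2 gained, for shRING1B with E2 luminal genes -0.28, genes near GREB1 -0.23. With the strict filter 2 were lost, for shRING1B with E2 G2/M genes -0.21, for the interaction early estrogen response -0.043, and 1 gained, for E2 in shCtrl genes near GREB1 0.10. Effective-length offsets lost 3, for E2 in shRING1B replication histones -0.11, for the interaction early estrogen response -0.12, developmental regulators 0.23, and gained 2, for shRING1B with E2 luminal genes -0.33, genes near GREB1 -0.17. The 4 libraries compared alone gained 1, for E2 in shRING1B PRC1 subunits 0.075, and the replicate block 3, for E2 in shRING1B basal and mesenchymal genes 0.14, heat shock -0.098, for the interaction receptor cofactors 0.11.

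Lists whose call changed without some library had these ranges of the median over the libraries left out. For shRING1B without E2 early estrogen response -0.38 to -0.19, luminal genes -0.59 to -0.43, G2/M genes -0.38 to -0.11, heat shock -0.23 to -0.13, ribosomal proteins -0.36 to 0.16, replication histones -0.23 to 0.016. For shRING1B with E2 luminal genes -0.45 to -0.17, G2/M genes -0.38 to -0.059, genes near GREB1 -0.34 to -0.13, ribosomal proteins -0.25 to 0.081. For E2 in shCtrl immediate early genes 0.17 to 0.45, developmental regulators -0.074 to 0.25, receptor cofactors -0.045 to 0.28, heat shock -0.21 to 0.027, ribosomal proteins -0.41 to 0.13, replication histones -0.30 to 0.037. For E2 in shRING1B HOX genes 0.029 to 0.31, developmental regulators 0.090 to 0.46, looping factors -0.082 to 0.089, R-loop factors -0.12 to -0.0044, luminal genes -0.047 to 0.15, fibroblast and immune genes 0.063 to 0.44, G2/M genes -0.21 to 0.17, G1/S genes -0.17 to 0.14, heat shock -0.14 to -0.0064, cholesterol synthesis -0.25 to 0.18, ribosomal proteins -0.27 to -0.0027, replication histones -0.26 to -0.0054. For the interaction early estrogen response -0.16 to -0.0013, immediate early genes -0.10 to 0.17, developmental regulators 0.0065 to 0.42, receptor cofactors -0.066 to 0.22, looping factors -0.12 to 0.045, luminal genes -0.041 to 0.15, G2/M genes -0.17 to 0.17, G1/S genes -0.19 to 0.18, heat shock -0.14 to 0.15, cholesterol synthesis -0.17 to 0.23, ribosomal proteins -0.28 to 0.26, replication histones -0.18 to 0.19. By the direction of the test, receptor cofactors (-0.045) and ribosomal proteins (0.13) reversed for E2 in shCtrl without replicate 1 of hormone-deprived shCtrl, ribosomal proteins (-0.013) also without replicate 2 of shCtrl with E2, and replication histones (-0.0054) for E2 in shRING1B without replicate 1 of shRING1B with E2.

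The 4C log2 ratios of E2 over hormone deprivation, for the lower side in shCtrl and shRING1B and the higher side in shCtrl and shRING1B, were 0.44, -1.71, -1.42 and 2.71. At the middle width they were 2.57, 1.42, 3.91 and 3.72 and at the largest 1.73, 1.28, 1.60 and 3.55, so the lower side of shRING1B and the higher side of shCtrl reversed. Wider windows also cover fewer positions, from -88 to 87 kb and from -76 to 75 kb, but at the smallest width over the latter the ratios were 0.41, -1.97, -1.38 and 2.47, so the lost positions were not the cause of the reversals. With 5 kb left out they were 0.44, -1.98, -1.42 and 2.45, with 20 kb 0.47, -1.20, -1.39 and 3.22, and with the values as deposited 0.87, -2.57, -0.99 and 1.86. The restriction to positions in all 4 files moved nothing, since the files list the same positions. Scaling by ERCC spike-ins was not run, since the tables held none. Depth limits the low-abundance genes, and 2 libraries per group limit the interaction. There 50.0% of 2-fold changes simulated in genes above a minimum mean count were recovered, a share that may be lower where fewer genes change.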
